A study of Micropterus salmoides with 9 samples.

How the data were processed

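Liver RNA of juvenile largemouth bass was sequenced in 9 libraries, 3 for each of 3 lead doses (0, 17.8 and 100 mg/L for 96 h). Per the labels' protocols, fish were acclimated for 14 days at 28 °C under 13 h of light and 11 h of dark, 90 fish in 3 tanks made up each dose, and libraries were made from 1 µg of total RNA with an Illumina kit for mRNA sequencing. Groups were taken from the sample titles and the series design.

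The files used were the authors' 3 tables of pairwise comparisons, their filtered versions, an annotation table and a table of how the assemblies of single libraries were merged. Per the file headers and gene names, the authors assembled the transcripts without a genome, merged the assemblies of the single libraries and annotated 81859 assembled genes against public databases. The aligner and counter are not given in the sources used here. The submitters' processing notes name the zebrafish build danRer7, with no role, and no coordinates of it were used. A table of largemouth bass genes for the assembly ASM1485139v1 matched 0 of the 48436 RefSeq accessions in the annotation, so names come from the authors' descriptions. A description names the best database match of a contig, which can be a paralog, and near-identical contigs can divide reads between them.

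Per the file headers, each deposited table gives for every assembled gene a length, a signal value for each of its groups, a log2 fold change, a p-value and an adjusted p-value from the authors' DESeq2 fit. The deposited signal values are group values of normalized reads: their log2 ratio equals the deposited log2 fold change for every gene, to rounding. They are therefore model values and not means of 3 libraries, and per-library values were not used here. The fold changes are shrunken toward 0, since a single read in 1 library gives a small finite fold. The deposited adjusted p-value equalled a Benjamini-Hochberg adjustment of all p-values in its table within the rounding of the table. Each table was normalized alone, so values were compared only within a table. The authors' filtered lists held genes with an adjusted p-value under 0.05 and at least a 2-fold change.

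The design fixed before the data were examined allowed for either counts or tables of comparisons. With tables of comparisons, the result was the authors' deposited DESeq2 adjusted p under 0.05 with no fold minimum and no test added. A standard error was computed for each gene as the size of its log2 fold change divided by the normal quantile of its deposited p-value. In simulated data the formula returned the known standard errors. That follows from the formula itself and does not test how the deposited p-values were made. In simulated tables of 66231, 65928 and 63200 genes with 200 genes changed, 2.13%, 4.85% and 1.96% of the calls were false.

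Size factors of the libraries were recovered from genes with a single read in 1 library. They lay between 1.24 and 1.28 in control libraries and between 0.732 and 0.910 in libraries of 17.8 mg/L in the first comparison. In the comparison of 100 mg/L with control they lay between 1.21 and 1.25 in control and between 0.726 and 0.988 at 100 mg/L. Multiplied by the group sums they gave about 12.4 M to 13.1 M reads per library, so depth was similar between doses. The factors were lower in lead-exposed libraries, where a larger share of the reads also fell on few genes. The 100 highest genes took 50.4% of the summed value at 17.8 mg/L against 36.6% in control, and 46.2% at 100 mg/L against 36.6%. The median log2 fold change of genes with a mean of at least 50 was 0.03 at both doses against control. The median implied standard error of called genes was 0.66, 0.53 and 0.80 in the comparisons of 17.8 mg/L with control, 100 mg/L with control and 100 with 17.8 mg/L.

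Membership in 36 gene lists was fixed as name patterns before the data were examined and matched to the authors' descriptions. The unit was the distinct description, represented by its assembled gene of the highest mean, which gave 20642, 20535 and 20263 descriptions in the same order. Each list was tested for higher and for lower genes with a two-sided Fisher's exact test against all descriptions tested, with Benjamini-Hochberg adjustment over the 72 tests of a comparison. The test treats genes as independent, and no correlation between genes could be estimated from group values. A gene with several descriptions, such as isoforms or contigs of 1 assembly cluster, counts as several members of a list. How far the list results rest on such repeats was not tested. In 50 simulated sets of calls a planted list passed in 50 at either dose against control and in 3 for the comparison of the doses, and an unplanted list passed in 2, 4 and 1. Conserved functional classes (KOG) and Gene Ontology terms with 10 to 500 descriptions were tested in the same way.

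The named genes followed, except where the text says otherwise, a rule fixed before the data were examined. It took the 3 called descriptions of the lowest p from each list that passed, the 5 highest and 5 lowest called descriptions that name a product and whose mean in the higher group was at or above the median mean, and a fixed set of sentinel genes of metal exposure. For the sentinel Cu-Zn superoxide dismutase the spelling of the pattern was widened after the tables were seen, and no description matched serum albumin. Values summed over a symbol add all assembled genes with the same symbol in the annotation. A symbol can join paralogs and can be that of a distant database match.

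Alternatives fixed beforehand were a stricter adjusted p of 0.01, a 2-fold minimum, the authors' filtered lists, a mean of at least 10 in the higher group, a length of at least 500 bases, 1 assembled gene per description, all assembled genes, and centring on the median of well expressed genes. Alternatives chosen after seeing the data were scaling each group to an equal total, the same with p recomputed from the moved fold change and implied standard error, sums over a symbol, and lists without descriptions caught by a wrong name. Simulated unchanged groups for the overlap of the doses were drawn from the implied standard errors with the covariance that shared controls give. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.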

Results

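Largemouth bass (Micropterus salmoides) is a predatory freshwater fish that is farmed for food, and lead is a toxic metal that the liver takes up and stores. Juvenile fish with a mean weight of 3 ± 0.2 g were kept for 96 h in water with 0, 17.8 or 100 mg/L lead. Liver mRNA was sequenced in 9 libraries, 3 per dose, and each dose was held in 3 tanks of 30 fish. The labels do not tie a library to a tank or give the number of fish behind it, so the p-values measure only the spread between these libraries. The tables hold 1 value per group and comparison for each assembled gene. The depth estimated from them was 12.4 M reads per control library, 13.1 M at 17.8 mg/L and 13.0 M at 100 mg/L. Every fold change below is given on the log2 scale with the standard error implied by its deposited p-value. No genome position is given, because the genes were assembled from the reads.

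The comparison of 17.8 mg/L lead with control asked which liver transcripts differ at the lower dose. Complement, clotting, acute-phase and interferon-response genes were over-represented among the higher transcripts of lead-exposed liver, and genes of fatty acid synthesis and immediate early transcription factors among the lower ones. CYP24A1, the mitochondrial enzyme that inactivates vitamin D hormones, rose by 7.45 ± 0.36 in the authors' deposited table, from a group value of 40.6 to 7114 normalized reads (DESeq2 adjusted p = 1.02e-91). Leukocyte cell-derived chemotaxin 2, a secreted liver protein that attracts neutrophils, rose by 4.17 ± 0.33 and haptoglobin, which binds free hemoglobin in plasma, by 5.20 ± 0.51 in the authors' deposited table. In the same direction, the contig named hepcidin-2, a peptide of the hepcidin family, rose by 4.76 ± 0.78 in the authors' deposited table (DESeq2 adjusted p = 3.32e-07). The contig named stearoyl-CoA desaturase 5 fell by 6.68 ± 0.90 in the authors' deposited table, and the contig named acyl-CoA desaturase fell by 6.30 ± 0.69. These enzymes put double bonds into fatty acids.

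Complement genes had 21 of 65 members higher, 0 lower and 44 not passing (two-sided Fisher's exact test, adjusted p = 1.38e-13). Adjusted over the list alone, 31 complement genes were higher and 1 lower. Complement C9, a part of the membrane attack complex, rose by 2.13 ± 0.30 and factor H-related protein 3 by 5.43 ± 0.75 in the authors' deposited table. C1q-like protein 2 rose by 5.25 ± 0.64 in the authors' deposited table, against 2.94 for the sum over its symbol, and it carries a C1q domain without being a subunit of the classical C1 complex. Coagulation genes were higher for 9 of 33 members with 0 lower (Fisher's exact test, adjusted p = 1.18e-05; 14 higher adjusted over the list alone). Fibrinogen beta chain rose by 1.47 ± 0.31 and plasma kallikrein by 3.42 ± 0.59 in the authors' deposited table. The kallikrein contig carries the symbol F11, whose sum was 2.10. Of 77 acute-phase and innate immunity genes, 17 rose, 1 fell and 59 did not pass (Fisher's exact test, adjusted p = 1.34e-08; 25 higher and 3 lower adjusted over the list alone). Toll-like receptor 22, a fish receptor for double-stranded RNA, rose by 3.92 ± 0.59 in the authors' deposited table.

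Interferon-response genes rose for 13 of 32 members with 0 lower (Fisher's exact test, adjusted p = 3.92e-10; 16 higher and 1 lower adjusted over the list alone). IFIT5, an antiviral RNA-binding protein, rose by 4.76 ± 0.64 and the interferon-induced very large GTPase 1 contig by 4.23 ± 0.40 in the authors' deposited table. The symbol sum of IFIT5 was 3.69. Antigen presentation genes rose for 5 of 33 members (Fisher's exact test, adjusted p = 0.0300; 6 adjusted over the list alone), among them an MHC class Ia antigen at 3.52 ± 0.44 in the authors' deposited table. Tapasin-related protein contigs with the shared symbol TAPBPL counted as separate risen members, at 2.49 ± 0.42 and 2.01 ± 0.53 in the authors' deposited table. Markers of lymphocytes rose for 5 of 30 members (Fisher's exact test, adjusted p = 0.0236; 10 adjusted over the list alone), among them immunoglobulin M heavy chain at 4.56 ± 0.90 in the authors' deposited table. A heavy chain variable region contig of the same assembly cluster counted as a further risen member, at 4.46 ± 0.97 in the authors' deposited table. Macrophage and neutrophil markers rose for 5 of 12 members (Fisher's exact test, adjusted p = 0.000273; 8 adjusted over the list alone). Matrix metalloproteinase-9, a protease released by neutrophils, rose by 4.47 ± 0.58 and a progranulin contig by 3.06 ± 0.78 in the authors' deposited table, the second against a symbol sum of 0.92. Hepatocyte markers rose for 9 of 21 members (Fisher's exact test, adjusted p = 1.83e-07; 9 adjusted over the list alone), but that list shares 6 members with the complement list, 5 with the coagulation list and 2 with the lipoprotein list. Serotransferrin, the iron carrier of plasma, rose by 1.64 ± 0.28 in the authors' deposited table. Fibroblast and stellate cell markers went the other way, with 5 of 33 lower and 0 higher (Fisher's exact test, adjusted p = 0.00374; 9 lower and 1 higher adjusted over the list alone). Collagen alpha-1(I) fell by 1.43 ± 0.37 and a collagen alpha-3(VI) contig fell by 1.58 ± 0.41 in the authors' deposited table. Another collagen alpha-3(VI) contig of the same assembly cluster counted as a further lower member, at -1.55 ± 0.42 in the authors' deposited table.

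Fatty acid synthesis genes fell for 13 of 51 members, 2 rose and 36 did not pass (Fisher's exact test, adjusted p = 3.92e-10; 18 lower and 3 higher adjusted over the list alone). An acetyl-CoA carboxylase 1 contig, from the enzyme of the committed step, fell by 4.49 ± 0.44 in the authors' deposited table, against -2.44 for the symbol. The list also holds liver fatty acid-binding protein, which carries fatty acids rather than making them. That contig fell by 5.13 ± 0.59 in the authors' deposited table, against -0.66 when the values of all assembled genes with its symbol were summed. Immediate early genes fell for 7 of 22 members with 0 higher (Fisher's exact test, adjusted p = 1.93e-06; 9 lower and 1 higher adjusted over the list alone). KLF6 fell by 3.09 ± 0.49, an EGR1-like contig fell by 3.59 ± 0.65 and a KLF4 contig fell by 3.53 ± 0.67 in the authors' deposited table. The KLF4 contig carries the symbol ZNF420, whose sum was -1.51. Lipoprotein genes rose for 5 of 33 members and fell for 1 (Fisher's exact test, adjusted p = 0.0300; 5 and 1 adjusted over the list alone). ANGPTL4, an inhibitor of lipoprotein lipase, rose by 3.60 ± 0.73 in the authors' deposited table. An ANGPTL4-like contig of the same assembly cluster counted as a further risen member, at 3.23 ± 0.77 in the authors' deposited table.

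Of the sentinel genes of metal exposure at 17.8 mg/L, heme oxygenase-1a, hepcidin-2 and serotransferrin rose and the others did not pass. ALAD, the heme-synthesis enzyme that lead inhibits, stood at -0.24 ± 0.41 and ferrochelatase at -0.06 ± 0.46 in the authors' deposited table, neither passing. Metallothionein, the metal-binding protein, stood at -0.44 ± 0.63 in the authors' deposited table (DESeq2 adjusted p = 0.900). Heme oxygenase-1a rose by 1.82 ± 0.49 in the authors' deposited table (DESeq2 adjusted p = 0.00914). Catalase at 0.16 ± 0.63, Cu-Zn superoxide dismutase at -0.35 ± 0.53, GST theta at 0.63 ± 0.40 and GPX4 at 0.61 ± 0.39 did not pass in the authors' deposited table. The heat shock cognate HSC71 at 0.20 ± 0.30, CYP1A1 at -0.77 ± 1.07 and vitellogenin Aa at -1.83 ± 1.11 did not pass in the authors' deposited table either. The CYP1A1 contig of 374 bases had values of only 1.77 normalized reads with lead and 3.03 in control, too few to judge a change.

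**Figure D1:**
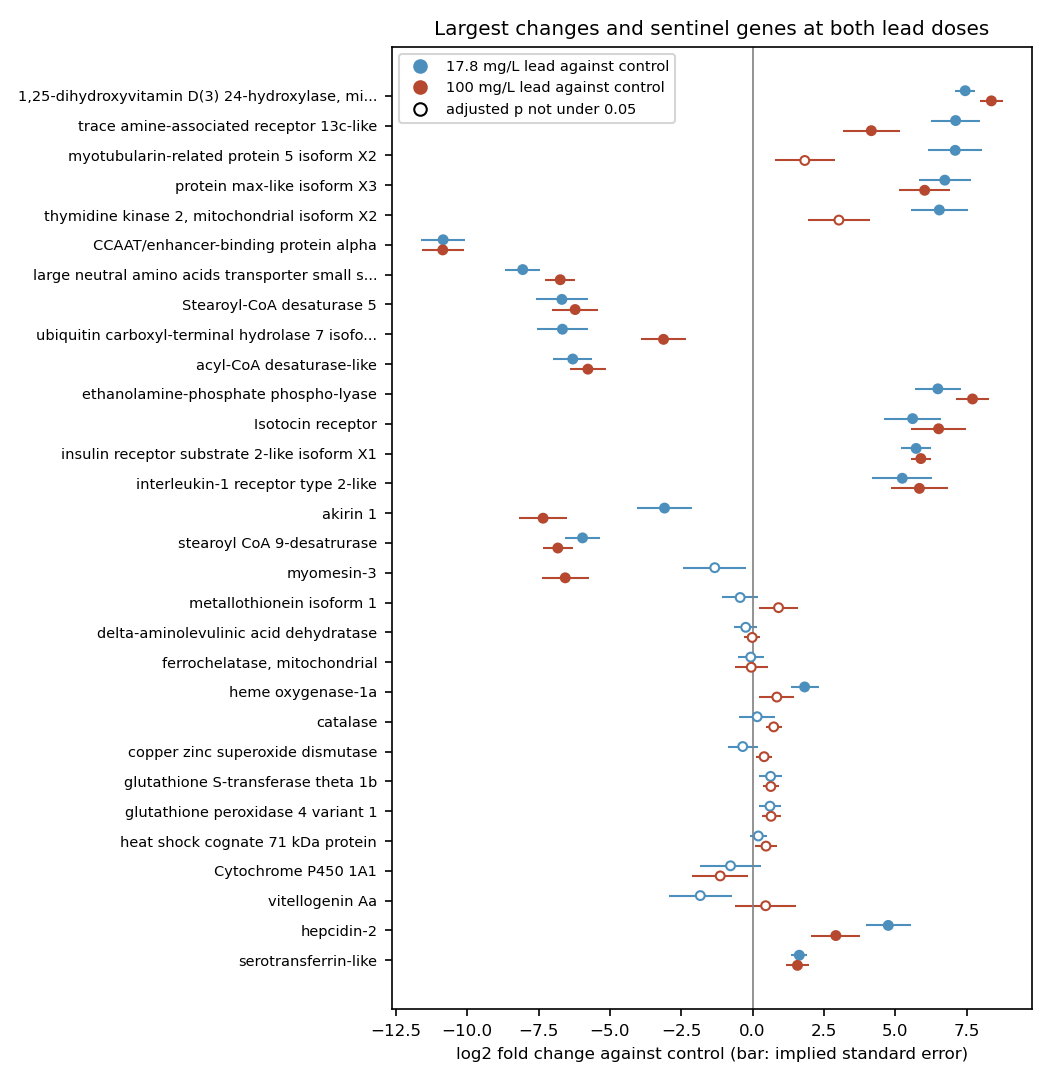
Log2 fold change against control (x axis) of the genes with the highest and lowest fold changes and of the sentinel genes of metal exposure (y axis), at 17.8 mg/L (blue) and 100 mg/L (red). Bars are implied standard errors, filled points have an adjusted p under 0.05 and open points do not; CYP24A1 lies at 7.45 and 8.37, while ALAD and ferrochelatase lie near 0 at both doses.

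Across the whole table, 2601 of 66231 assembled genes passed at 17.8 mg/L, 1743 higher and 858 lower (67.0% higher), and 353 of them had no description. Several of the highest and lowest contigs shared a symbol with other contigs. The contig of CEBPA, a liver transcription factor, fell by 10.85 ± 0.78 in the authors' deposited table, against -2.60 for the symbol. An amino acid transporter contig, SLC43A2, fell by 8.06 ± 0.62 in the authors' deposited table, against -2.16 for the symbol. Contigs of MAX and USP7, at 6.74 ± 0.90 and -6.67 ± 0.90 in the authors' deposited table, came to 0.23 and -0.37. Contigs of a trace amine-associated receptor, myotubularin-related protein 5 and thymidine kinase 2 rose by 7.12 ± 0.86, 7.10 ± 0.94 and 6.55 ± 1.01 in the authors' deposited table, against symbol sums of 3.09, 1.25 and 2.40. The receptor contig carries the symbol Rac2 and the myotubularin contig sbf2, so their sums are not sums over the gene named. Scaling each group to the same total lowered every fold change by the same amount, a shift of -0.66, and with p recomputed it gave 888 genes higher and 4087 lower (17.8% higher). Under that scaling the adjusted Fisher p was 0.303 for antigen presentation, 0.064 for lymphocyte markers, and 0.069 for lipoproteins and for macrophage and neutrophil markers. The lipoprotein median went from 0.24 to -0.42, while the medians of the other passing lists kept their sign. Among the sentinel genes that did not pass, catalase, GST theta, GPX4 and HSC71 went from above to below 0.

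The comparison of 100 mg/L lead with control asked the same question at the higher dose. Complement, clotting and interferon-response genes were again over-represented among the higher transcripts and fatty acid synthesis genes among the lower ones. Genes of ribosomal proteins and of amino acid breakdown were over-represented among the higher transcripts as well, but neither list passed as higher with equal totals per group. CYP24A1 rose by 8.37 ± 0.40 in the authors' deposited table, from 44.9 to 14871 normalized reads (DESeq2 adjusted p = 2.55e-90). IRS2, an adaptor of the insulin receptor, rose by 5.90 ± 0.35 in the authors' deposited table (DESeq2 adjusted p = 4.01e-58), and its symbol sum was 3.64. A stearoyl-CoA desaturase contig with a control value of 26736 normalized reads fell by 6.83 ± 0.53 in the authors' deposited table, to 235.6.

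Of 66 complement genes, 18 rose, 1 fell and 47 did not pass at 100 mg/L (Fisher's exact test, adjusted p = 5.56e-09; 23 higher and 2 lower adjusted over the list alone). Complement C5 rose by 2.10 ± 0.29 and C4-B by 1.63 ± 0.31 in the authors' deposited table. The gene that fell, named after its value was seen, was a C1q and tumor necrosis factor-related protein, a secreted hormone-like protein outside the complement cascade. The genes that fell in the coagulation and interferon lists were also caught by their names alone. Coagulation genes rose for 13 of 33 members and fell for 1 (Fisher's exact test, adjusted p = 7.93e-09; 20 higher and 1 lower adjusted over the list alone). A factor XI contig rose by 3.08 ± 0.52 and a factor IX contig by 0.98 ± 0.22 in the authors' deposited table. Acute-phase and innate immunity genes rose for 10 of 73 members and fell for 2 (Fisher's exact test, adjusted p = 0.00921; 13 and 2 adjusted over the list alone). Haptoglobin rose by 3.08 ± 0.47 and leukocyte cell-derived chemotaxin 2 by 3.82 ± 0.60 in the authors' deposited table. Lysozyme C, an antibacterial enzyme, rose by 2.95 ± 0.48 in the authors' deposited table. Interferon-response genes rose for 7 of 30 members and fell for 1 (Fisher's exact test, adjusted p = 0.00243; 12 higher and 1 lower adjusted over the list alone), with IFIT5 at 4.33 ± 0.62 in the authors' deposited table. The symbol sum of IFIT5 was 3.29. Antigen presentation genes rose for 4 of 31 members without passing as a list (Fisher's exact test, adjusted p = 0.149; 6 adjusted over the list alone).

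Ribosomal protein genes rose for 23 of 89 members with 0 lower at 100 mg/L (Fisher's exact test, adjusted p = 1.83e-10), and 68 rose adjusted over the list alone. The changes were small and close together, with a list median of 0.75 and quartiles of 0.61 and 0.83. With equal totals per group the median was 0.16 and the list did not pass as higher. RPL3 rose by 0.98 ± 0.27, RPL12 by 0.89 ± 0.24 and RPS3A by 0.90 ± 0.26 in the authors' deposited table. At 17.8 mg/L the same list had 0 of 89 members passing and a median of 0.40 (-0.27 with equal totals per group). Genes of amino acid breakdown rose for 12 of 69 members and fell for 2 (Fisher's exact test, adjusted p = 0.000437; 15 and 4 adjusted over the list alone). Liver glutaminase rose by 2.88 ± 0.55, urocanate hydratase of histidine breakdown by 1.59 ± 0.31 and cystathionine beta-synthase by 1.09 ± 0.24 in the authors' deposited table, and the symbol sum of the glutaminase was 1.28. Lipoprotein genes rose for 6 of 33 members with 0 lower (Fisher's exact test, adjusted p = 0.0172; 6 adjusted over the list alone). Apolipoprotein C-II, the activator of lipoprotein lipase, rose by 2.12 ± 0.46 in the authors' deposited table. An apolipoprotein A-IV contig rose by 5.38 ± 0.84 in the authors' deposited table, against 1.31 for the symbol.

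Fatty acid synthesis genes fell for 17 of 51 members at 100 mg/L and 2 rose (Fisher's exact test, adjusted p = 5.97e-10; 22 lower and 3 higher adjusted over the list alone). The acyl-CoA desaturase contig fell by 5.77 ± 0.63 and the stearoyl-CoA desaturase 5 contig fell by 6.22 ± 0.80 in the authors' deposited table. Immediate early genes fell for 3 of 21 members, rose for 1 and did not pass as a list (Fisher's exact test, adjusted p = 0.190; 3 lower and 1 higher adjusted over the list alone). Fibroblast and stellate cell markers fell for 7 of 33 members and rose for 1 (Fisher's exact test, adjusted p = 0.00365; 13 lower and 1 higher adjusted over the list alone). Decorin fell by 2.15 ± 0.54 and biglycan fell by 1.26 ± 0.36 in the authors' deposited table, and both are small proteoglycans of the collagen matrix. Macrophage and neutrophil markers rose for 4 of 12 members (Fisher's exact test, adjusted p = 0.00941; 6 adjusted over the list alone), with matrix metalloproteinase-9 at 4.49 ± 0.79 and myeloperoxidase at 2.07 ± 0.64 in the authors' deposited table. Hepatocyte markers rose for 8 of 21 members (Fisher's exact test, adjusted p = 2.12e-05; 10 adjusted over the list alone). Lymphocyte markers rose for 1 of 27 members and did not pass as a list (Fisher's exact test, adjusted p = 1; 1 adjusted over the list alone).

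Among the sentinel genes at 100 mg/L, hepcidin-2 rose by 2.92 ± 0.85 and serotransferrin by 1.57 ± 0.41 in the authors' deposited table. Metallothionein at 0.91 ± 0.70, ALAD at -0.01 ± 0.27, ferrochelatase at -0.05 ± 0.57 and heme oxygenase-1a at 0.85 ± 0.61 did not pass in the authors' deposited table. Catalase at 0.74 ± 0.28 (DESeq2 adjusted p = 0.0977), Cu-Zn superoxide dismutase at 0.40 ± 0.27, GST theta at 0.64 ± 0.29 and GPX4 at 0.65 ± 0.33 did not pass in the authors' deposited table. HSC71 at 0.47 ± 0.37, CYP1A1 at -1.13 ± 0.99 and vitellogenin Aa at 0.46 ± 1.06 did not pass in the authors' deposited table either. The CYP1A1 values were again low, 1.29 normalized reads at 100 mg/L and 2.84 in control.

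**Figure D2:**
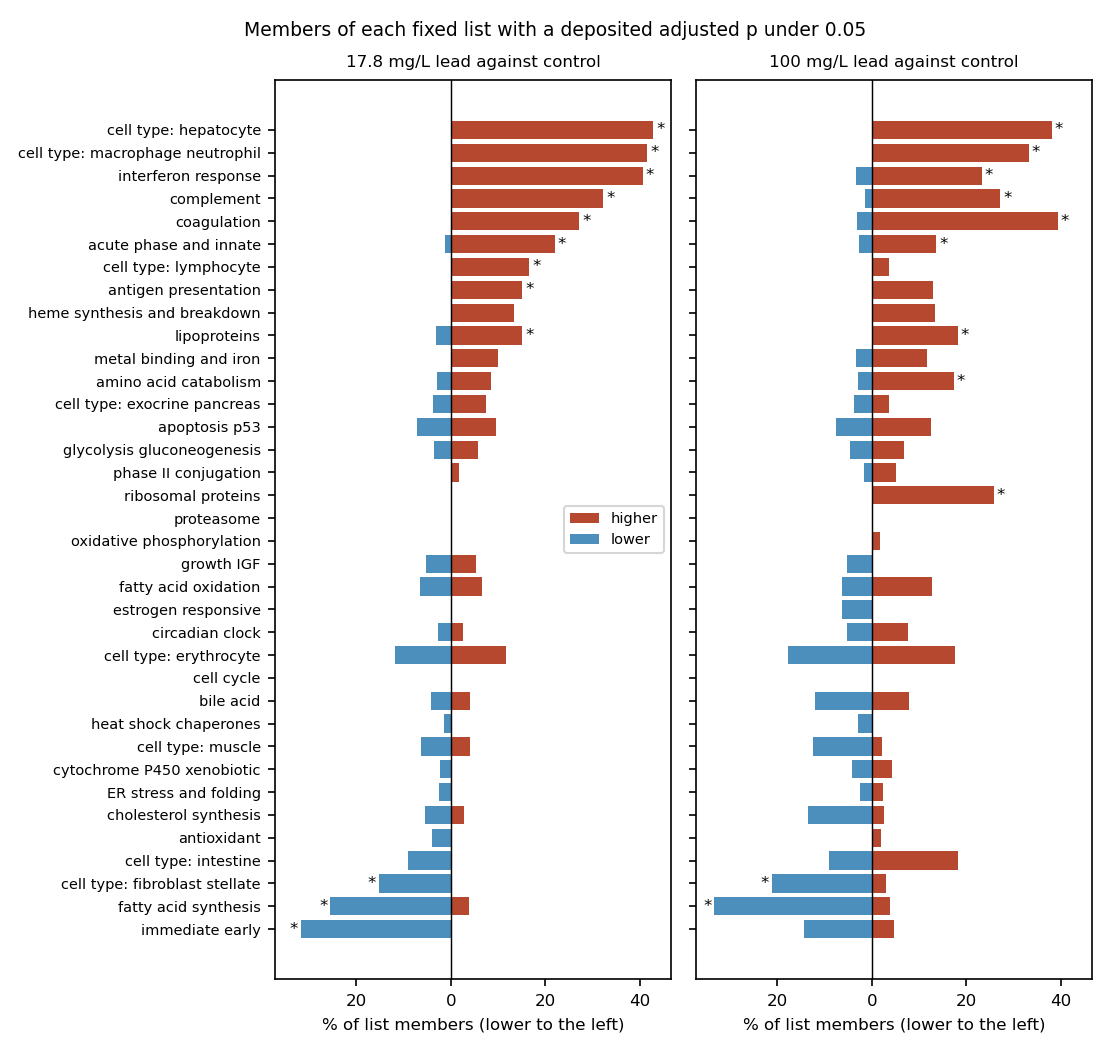
Percent of the tested members of each of 36 fixed gene lists (y axis) whose deposited adjusted p was under 0.05, higher to the right and lower to the left (x axis, % of members), at 17.8 mg/L (left) and 100 mg/L (right). Asterisks mark lists whose Fisher test passed in that direction: 21 of 65 complement genes were higher at 17.8 mg/L, and 23 of 89 ribosomal protein genes at 100 mg/L.

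In total, 3716 of 65928 assembled genes passed at 100 mg/L, 2210 higher and 1506 lower (59.5% higher), and 507 of them had no description. A CEBPA contig fell by 10.86 ± 0.74 in the authors' deposited table, against -2.10 for the symbol, and the SLC43A2 contig fell by 6.74 ± 0.53, against -4.0. Contigs of akirin 1 and myomesin-3 fell by 7.34 ± 0.83 and fell by 6.57 ± 0.83 in the authors' deposited table, against -0.75 and -0.54. The contig of ethanolamine-phosphate phospho-lyase rose by 7.71 ± 0.59 in the authors' deposited table, while the sum over its symbol was -1.38. An isotocin receptor contig rose by 6.52 ± 0.95 and the decoy receptor IL1R2 by 5.85 ± 0.99 in the authors' deposited table. Equal totals per group, a shift of -0.59, gave 1022 genes higher and 5598 lower with p recomputed (15.4% higher). Under that scaling the ribosomal list had a median of 0.16 and an adjusted Fisher p of 0.654, amino acid breakdown 0.110, and macrophage and neutrophil markers 0.376. The median of the acute-phase and innate immunity list went from 0.51 to -0.08 and that of amino acid breakdown from 0.59 to -0.00, while the medians of the other passing lists kept their sign. Cu-Zn superoxide dismutase, HSC71 and vitellogenin Aa, which did not pass, went from above to below 0.

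The direct comparison of 100 with 17.8 mg/L lead asked which transcripts differ between the doses. It called 88 of 63200 assembled genes, 50 higher and 38 lower at 100 mg/L, against 1799 at an unadjusted p under 0.05 by the same DESeq2 test. The unadjusted count is below what evenly spread p-values would give, so it is no sign of further differences between the doses. It does not speak against them either, because the median mean was 6.47 normalized reads and p-values of such low genes need not spread evenly. With 1 assembled gene per description 2 were higher and 9 lower. Mitochondrial uncoupling protein 2, a carrier of the inner membrane, had a contig higher by 2.91 ± 0.45 in the authors' deposited table (DESeq2 adjusted p = 6.71e-07), and its 7 assembled genes together came to 0.66. A MEF2A contig was higher by 3.81 ± 0.83 in the authors' deposited table, against -0.11 for the symbol. Contigs of FRYL, SPAG9 and NCOA3 fell by 4.14 ± 0.82, fell by 4.08 ± 0.79 and fell by 3.60 ± 0.84 in the authors' deposited table, against -0.15, -0.06 and -0.21. Contigs of ninein and of a DDIT4-like gene fell by 3.48 ± 0.85 and fell by 3.18 ± 0.78 in the authors' deposited table, against -1.88 and 0.15. Haptoglobin stood at -1.99 ± 0.56 (DESeq2 adjusted p = 0.192), hepcidin-2 at -1.27 ± 0.82 and CYP24A1 at 0.97 ± 0.43 in the authors' deposited table, none passing. Ribosomal protein genes had a median of 0.35, with 85 of 89 above 0 and 0 passing.

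Across all 36 lists, 1 member passed in the direct comparison of the doses, named after its value was seen, a contig of the branched-chain 2-oxoisovalerate dehydrogenase at -2.42 ± 0.58 in the authors' deposited table (DESeq2 adjusted p = 0.0271), against 0.05 for the sum over its symbol. Adjusted over each list alone, 3 members were higher and 3 lower. The adjusted p of Fisher's exact test was 1 for each list, and in simulated calls of this number a planted list passed in 3 of 50 draws, so a list-wide difference between the doses was not detectable with so few calls.

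**Figure D3:**
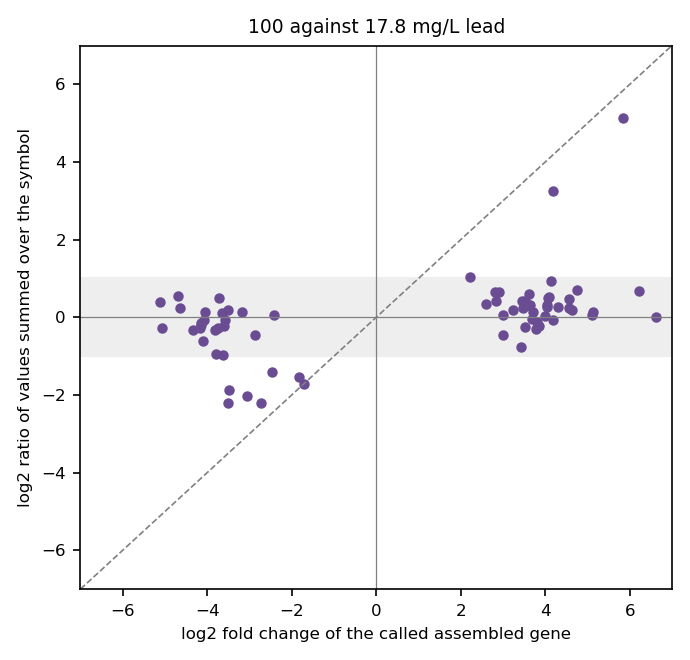
Log2 fold change of 70 assembled genes called between 100 and 17.8 mg/L lead (x axis) against the log2 ratio of the values summed over all assembled genes with the same symbol (y axis). The dashed line marks equal values and the grey band a summed change under 2-fold, where 60 of the 70 points lie.

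The calls at the doses were then set side by side over 20227 descriptions tested in both comparisons with control. Each was represented by its assembled gene of the highest mean over both comparisons, so the counts differ slightly from those of a single comparison. At 17.8 mg/L 1109 descriptions were called and at 100 mg/L 1767, and 654 were called at both, 391 higher, 263 lower and 0 in opposite directions. Independent lists of these sizes would share 30.0 higher and 18.5 lower. Both comparisons used the same 3 control libraries, and unchanged groups simulated against shared controls gave 2 shared calls at the same p cutoffs and 0 after adjustment (20 simulations). The fold changes had a correlation of 0.751 across genes, which are not independent replicates, against 0.435 simulated, and a covariance of 0.798 against 0.201. Without values per library the 3 controls could not be divided between the comparisons, so the part of the excess due to shared controls was not measured. Of the 2222 descriptions called at either dose, 98.1% had the same sign at both and 61.0% had the larger fold at 100 mg/L. In the simulated unchanged groups, genes selected by the same p cutoffs at either dose gave 93.6% and 56.6%, and those shares come from shared controls and selection alone.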

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

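The tests of the following patterns were chosen after the results were seen, except the test of gene length, and the summed share in the test of immune cells was added after its share of markers was seen. The direct comparison of the doses differed for 7 of the named contigs: UCP2 at 2.91, MEF2A at 3.81, FRYL at -4.14, SPAG9 at -4.08, NCOA3 at -3.60, ninein at -3.48 and DDIT4-like at -3.18 in the authors' deposited table. Chosen after its values were seen, a purine nucleoside phosphorylase contig had 8.15 at 17.8 mg/L, -0.40 at 100 mg/L and -5.11 between the doses in the authors' deposited table, while the 8 assembled genes of its symbol came to 0.39.

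Calls between the doses lay mostly in genes with several contigs, since 73 of the 88 were in assembly clusters, 83.0% against 38.5% of all tested genes (two-sided Fisher's exact test, p = 1.28e-17). All tested genes include many low ones (median mean 6.47), and the share in clusters was not computed for calls against control. There 1678 of 1889 and 2390 of 2788 calls with a symbol shared it, at 17.8 and 100 mg/L, against 70 of 71 between the doses. The median size of the change dropped from 3.73 to 0.32 once values were summed over the symbol. That argues against a change of the whole gene's level only where a symbol stands for 1 gene, since abundant contigs set the sum. Contigs named after their values were seen kept the change in the sum, among them PAN2 at -1.71, AVPI1 at 3.26 and XIRP2 at 5.12. Of 70 called genes with a shared symbol, 85.7% came under 2-fold after summing, against 40.1% and 37.8% of calls of like fold at 17.8 and 100 mg/L against control (Fisher's exact test, p = 2.60e-14 and 9.57e-16), so a different division of reads among contigs is a candidate explanation. Far more genes were called against control, where the other contigs of a symbol can change as well, so the contrast does not isolate a division of reads. Different alleles or splice forms in the fish sampled cannot be told apart from it: a sibling contig moved the other way in 26.03% of the clustered calls, which decides nothing without reads per library. A symbol that joins paralogs would also hide a change of its minor member.

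Ribosomal protein genes had a median of 0.75 at 100 mg/L, with 23 of 89 higher, 66 not passing and 78 above 0, and the list no longer passed as higher at an adjusted p of 0.01, with a 2-fold minimum or with equal totals. Short length is argued against, because the list lay at the 100 percentile of 10000 random lists of like expression and length, whose median was 0.18. The 99.94 percentile among lists of like expression alone was set aside as a test of scaling after it was seen, since a shift of all genes cannot change a rank. Whether the level itself rose cannot be told apart from the scaling of the libraries, since with equal totals the median was 0.16 and the list did not pass as higher (adjusted Fisher p = 0.654), while ribosomal genes were under-represented among lower genes, with 0 of 89 lower at 100 mg/L (adjusted Fisher p = 1.06e-05) and 2 of 89 at 17.8 mg/L (0.0258). Random lists take genes as independent, so chance variation shared by ribosomal genes among 3 libraries stays open, and a higher level relative to other genes with lead may be the biological explanation.

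Macrophage and neutrophil markers were over-represented among higher genes and fibroblast markers among lower genes at both doses, while lymphocyte markers passed at 17.8 mg/L only, and with equal totals the macrophage and neutrophil list passed at neither dose (adjusted Fisher p = 0.069 and 0.376). A lower share of hepatocytes alone would raise the markers of every other cell type alike. The fibroblast list instead had a median of -1.07 at 100 mg/L with quartiles of -1.69 and -0.22. Those lay below the lower quartile of 0.45 of the macrophage and neutrophil list. That fall is part of the pattern as it was chosen, so it cannot decide on a lower share joined with other changes. More blood left in the liver would raise the summed share of erythrocyte genes, which was 0.458 of control at 17.8 mg/L and 0.439 at 100 mg/L. Single hemoglobin contigs went both ways. The erythrocyte list had 2 of 17 members higher and 2 lower at 17.8 mg/L, and 3 higher and 3 lower at 100 mg/L. The share also depends on expression within erythrocytes, so more blood is not excluded. More macrophages, neutrophils and lymphocytes may lie behind the rise and cannot be told apart from higher expression in the same cells: 66.7% and 50% of the macrophage and neutrophil markers passed at 17.8 and 100 mg/L when adjusted over the list alone. Their summed share was 1.38 and 1.06 times control, and that of lymphocyte markers 5.997 and 1.51 times. All summed shares here, those of erythrocyte genes included, divide by the total of the group. They are thus on the scale of equal totals, while the list medians and marker counts are on the deposited scale.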

How the results depend on the processing

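The alternatives based on symbols, equal totals and wrong names were chosen after seeing the data. No paired analysis was possible because the tables give group values only. For the same reason the other normalization, the other count test, the replicate block and leaving out single libraries were not run, and other splits of the libraries were not counted. In the comparisons of 17.8 mg/L with control, 100 mg/L with control and 100 with 17.8 mg/L, the 2601, 3716 and 88 calls became 1491, 2069 and 56 at an adjusted p of 0.01, by construction. They became 1121, 1765 and 11 with 1 assembled gene per description, where the share of higher genes was 63.2%, 50.4% and 18.2%, and 1192, 1703 and 11 when the symbol sum also had to change 2-fold the same way, where only the 1889, 2788 and 71 calls with a symbol could count. Equal totals with p recomputed gave 4975 and 6620 calls against control. That setting moved every fold change by -0.66 and -0.59 and kept the implied standard errors, so the added lower calls follow by construction. Which scaling is right was not tested. A minimum mean (3325, 4644 and 100 calls), a 2-fold minimum (2597, 3557 and 88), the authors' lists and a minimum length (2552, 3659 and 88) stayed within 1.5 times, and centring moved no call to the other sign. Of the fixed lists, 12 and 11 passed at 17.8 and 100 mg/L, and with all assembled genes 20 and 24 did, where redundant contigs are counted separately. The shared calls numbered 654, against 1432 over all assembled genes and 355 at an adjusted p of 0.01. Summed over the symbol, 3 named contigs changed sign: ethanolamine-phosphate phospho-lyase to -1.38, MEF2A to -0.11 and the DDIT4-like gene to 0.15, and the cause was not tested. Another 39 fold changes of called named contigs moved by at least their implied standard error, and 33 stayed within it. With equal totals 54 moved that far and 44 did not. Of 23 list calls, 6 were lost at an adjusted p of 0.01, 7 with equal totals, 1 with a 2-fold minimum, 1 with a minimum mean and 0 without wrong-name matches. That removal left C1q-like protein 2 in the complement list and liver fatty acid-binding protein in the fatty acid synthesis list. Ribosomal proteins at 100 mg/L had an adjusted Fisher p of 1 at the stricter threshold, 0.578 with a 2-fold minimum and 0.654 with equal totals. The median implied standard error of a called gene was 0.66, 0.53 and 0.80 in the same order, and what depth limits was not tested.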

Other observations

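The following genes were named after their values were seen, and no list that holds them passed as a whole in the main test. Ferroportin, the iron exporter, rose by 2.96 ± 0.48 at 17.8 mg/L and 2.48 at 100 mg/L in the authors' deposited table, and a hephaestin-like ferroxidase by 3.42 and 2.93. At 100 mg/L a ferritin M contig rose by 2.03 and transferrin receptor 1 by 2.13 in the authors' deposited table. The metal binding and iron list as a whole rose for 6 of 60 members at 17.8 mg/L and 7 of 60 at 100 mg/L and did not pass (Fisher's exact test, adjusted p = 0.0920 and 0.0758), and 1 of its risen members at each dose was a pyruvate dehydrogenase kinase caught by its name. IGFBP1, which binds insulin-like growth factors, rose by 6.09 at 17.8 mg/L in the authors' deposited table, where its list of growth factor genes had 1 of 19 members higher and 1 lower, against 0 higher and 1 lower at 100 mg/L. Liver CPT1, the entry enzyme of mitochondrial fatty acid oxidation, rose by 2.23 and 2.27 in the authors' deposited table at the lower and the higher dose. Cholesterol 7-alpha-monooxygenase, the rate-limiting enzyme of bile acid synthesis, fell by 3.47 and fell by 3.36 in the authors' deposited table, while the contig of its repressor SHP rose by 3.73 and 2.62. GADD45 gamma, a growth arrest gene, rose by 4.16 and 4.73 in the authors' deposited table. The fatty acid oxidation list had 3 of 46 members higher and 3 lower at 17.8 mg/L, and 6 of 47 higher and 3 lower at 100 mg/L. For bile acids these were 1 and 1 of 24, then 2 and 3 of 25. For apoptosis they were 4 and 3 of 42, then 5 and 3 of 40.

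No list test passed at either dose for heme metabolism, antioxidants, conjugation, cytochrome P450, heat shock, endoplasmic reticulum stress, apoptosis, cholesterol synthesis, fatty acid oxidation, bile acids, glycolysis, proteasome, respiratory chain, estrogen response, cell cycle, growth factors, circadian clock, or markers of erythrocytes, exocrine pancreas, muscle and intestine. Of 121 respiratory chain genes 0 were called at 17.8 mg/L, and of 120 at 100 mg/L 2 rose. With equal totals and p recomputed, chosen after seeing the data, metal and iron genes (adjusted Fisher p = 0.0213 and 0.0226) and apoptosis genes (0.0288 and 0.0276) passed as higher at both doses, and muscle markers passed as lower at 100 mg/L (16 of 48, adjusted Fisher p = 0.0294). The metal and iron passes rest on 5 of 60 members at each dose, and descriptions caught by a wrong name were not removed there. In that setting antigen presentation genes were under-represented among lower genes at 100 mg/L (0 of 31, adjusted Fisher p = 0.0349). Among KOG classes, amino acid metabolism was over-represented among higher genes at 17.8 mg/L (32 of 394) and 100 mg/L (39 of 392; Fisher's exact test, adjusted p = 4.34e-05 and 2.25e-05). Extracellular structures were over-represented among lower genes (21 and 36 of 373; 0.000847 and 0.000445). At 17.8 mg/L 39 of 532 defense genes were higher (adjusted p = 4.34e-05). At 100 mg/L 47 of 509 genes of translation and ribosome were higher (2.25e-05), a class under-represented among higher genes at 17.8 mg/L (4 of 507; 0.00424), and 73 of 921 cytoskeleton genes were lower (8.95e-05). RNA processing was under-represented among higher genes at 17.8 mg/L (5 of 632; 0.000847) and among lower genes at 100 mg/L (7 of 632; 2.25e-05), and other classes that passed are not described here. Of 85 Gene Ontology terms 2 passed at 17.8 mg/L, extracellular region higher (adjusted p = 0.0305) and calcium ion binding lower (0.0235), and of 89 terms 0 passed at 100 mg/L, where the lowest adjusted p was 0.0842.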
